A study of Mus musculus with 12 samples.

How the data were processed

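The data are 12 RNA-seq libraries of the mouse BV2 microglial line in 4 groups of 3, WT and Atg5 KO cells kept in medium or given 1 U/mL IFNγ for 24 h. Per the labels' protocols, cytosolic RNA was taken after a mild lysis that leaves nuclei behind, poly-A RNA was enriched, cDNA was made with barcoded oligo-dT primers, libraries were pooled by their Actb level, and each replicate was made independently. The number of KO clones is not given.

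The authors deposited 1 table of log2 values with Ensembl gene identifiers, symbols and Entrez numbers. Per the submitters' processing notes, FastQC 0.11.2, STAR (no version), HTSeq 0.6.1 and DESeq2 1.10.1 were used on GRCm38; the notes give no roles, annotation release or filter. The values were checked and are log2 of a count divided by a size factor of the library, plus 1: 100% of them turn back into whole reads within 0.01 of a read. The reads recovered this way gave the depth, 3329849 to 7330435 per library. Over 3 libraries, a group with no read was set to a floor of 3 reads, and a fold against it is a lower bound; with 1 to 3 reads the ratio of normalised reads is given with a 95% interval. Polymerase chain reaction copies are not independent molecules, so floors and intervals cover counting error only.

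Of 46078 genes 16924 had a read. Genes with a log2 value of at least 3 in at least 3 of the 12 libraries were kept, 10981 in all. The table gives no symbol for 735 genes and a number, as spreadsheets make from some names, for 27. The 13 mitochondrial genes stand at 0 in every library, so no mitochondrial share could be used as a sign of RNA quality. Positions came from GENCODE release M21, which holds 45143 of the identifiers and 10952 of the kept ones. Some families named here, such as the guanylate-binding proteins, immunity-related GTPases, Serpina3 and class I genes, hold close paralogs that can share reads.

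The test was limma 3.58.1 in R 4.3.3 on the deposited log2 values: 1 model with a mean per group and 8 residual degrees of freedom, empirical Bayes with a mean-variance trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all kept genes. Adjusted p in the text are limma's unless camera, fry or voom is named. The comparisons are IFNγ against medium in each genotype, KO against WT in each treatment, and the difference between the responses. Errors of log2 changes are limma's standard errors, and errors of group means are standard deviations of 3 libraries. Errors of list medians in the closing section are taken over genes, which are not independent replicates. On simulated data of this size limma recovered 86%, 89%, 79% and 84% of genes changed 4-fold in the first 4 comparisons and 31%, 43%, 34% and 46% of those changed 2-fold. False calls made up 2.59% to 7.04% of all calls. The simulated libraries were drawn independently, with no weakly responding library and no letter effect. Genes of like level shared 1 spread, and each rate comes from a single draw with 100 genes changed by each fold. Recovery and false calls in the real data may therefore differ.

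Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 22 lists within a comparison, with an estimated correlation and with fry as alternatives. Of the 23 lists, that of mitochondrial transcripts had no kept member and was not tested; the others hold IFNγ signalling, guanylate-binding proteins, immunity-related GTPases, both MHC classes, antiviral genes, chemokines, TNF and NF-kB signalling, cell death, antimicrobial effectors, autophagy, lysosome, NRF2, stress response, p53, cell cycle, cholesterol, glycolysis, microglial identity, complement, nuclear-retained RNAs and immediate early genes. C1qa, C1qb and C1qc are in the identity and the complement list. Camera called 17 lists with IFNγ in WT cells (15 with an estimated correlation, 18 by fry), 15 in KO cells (15 and 15), 5 between untreated genotypes (0 and 1), 6 between treated genotypes (0 and 3) and 1 for the difference in response (0 and 0). Between treated genotypes fry called the antiviral, lysosome and nuclear-retained lists, each with an adjusted p of 0.0463; fry does not compare a list with other genes. Median and mean differed in sign in a few lists that camera did not call, such as cell death between untreated genotypes and chemokines for the difference in response. Another 8 lists hold the 56 markers of other cell types.

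The groups, the tests, the lists, the markers, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each comparison, the 8 higher and 8 lower called genes with the largest change, a mean of at least 5 in the higher group and no overlap of the groups, up to 2 called members of each list with the largest change, and 10 genes whatever their result. A few genes that the rule names are left out of the text. Genes named outside it were chosen after their values were seen: the markers Lck, Cnp, Kdr and Vwf, members added to complete a list's count (Ccl24, Ccl9, Cxcl14, Mdm2, Sesn1 in WT and Gstm1 in KO cells, Ccnd1, Hp, Aldoc, C1qc), Hnrnph1 and AI506816, and those the closing section adds (Abhd6, Ush1c, Apoe, Trem2, Tgtp1, Rtp4).

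Alternatives were no filter and a stricter filter at a log2 of 5, 8 in place of 1 added before the log, equal medians, quantile normalisation, no variance trend, robust empirical Bayes, only the compared groups, the replicate letter as a block, a log2 change of at least 1, and leaving out each library. Chosen after the data were seen were voom on the recovered reads and leaving out both IFNγ libraries of letter C. The letters were not used as pairs. No library was left out of the results in the report. Scripts ran in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.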

Results

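Expression was measured in BV2, an immortalised mouse microglial line, as wild type (WT) cells and as a knockout (KO) of Atg5, which is needed to form autophagosomes. Both genotypes received medium alone or 1 U/mL interferon gamma (IFNγ), a cytokine that activates macrophages, for 24 h. There were 3 libraries in each of the 4 groups, and replicates carry the letters A, B and C. The libraries were made from the 3' ends of cytosolic poly-A RNA. In WT cells the recovered reads of A, B and C came to 7250217, 6374229 and 5328094 in medium and to 4206978, 5228009 and 4554009 with IFNγ. In KO cells they came to 3329849, 6814208 and 5059603 in medium and to 4851867, 5707089 and 7330435 with IFNγ. Values are log2 of the normalised count plus 1, and 10981 of the 46078 listed genes were measured well enough to test.

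The axis of largest variation held 40.3% of the variance and parted the treatments, with the IFNγ libraries between 22.2 and 56.3 and the medium libraries between -45.9 and -33.5. WT IFNγ C stood lowest among the treated libraries at 22.2, while WT IFNγ A and B stood at 55.3 and 56.3. The next axis held 11.6% and parted the genotypes. Of 56 marker genes of fibroblasts, neurons, astrocytes, oligodendrocytes, T cells, B cells, epithelial and endothelial cells, 34 had no read and 5 could be tested. Among these, the T cell kinase Lck (log2 change 1.83, adjusted p = 0.00861) and the myelin enzyme Cnp (1.08, adjusted p = 0.0411) rose with IFNγ in WT cells. Kdr, the endothelial VEGF receptor, was lower in untreated KO than in untreated WT cells (-1.43, adjusted p = 0.0104) and rose with IFNγ in KO cells (1.12, adjusted p = 0.00941). Vwf, a clotting protein of endothelial cells, passed in none of the 4 comparisons of pairs of groups.

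The transcript of the targeted gene, Atg5 (ENSMUSG00000038160, chromosome 10, 44268358 to 44364291 on GRCm38), was present at like levels in both genotypes. In medium it stood at 8.48 ± 0.11 (SD, n = 3) in WT and 8.85 ± 0.17 in KO cells, a difference of 0.37 (SE 0.17, adjusted p = 0.595). With IFNγ it stood at 8.91 ± 0.05 and 8.78 ± 0.05, a difference of -0.13 (SE 0.17, adjusted p = 0.817). Reads from the 3' end of a transcript need not cross an edited site, so these values are no check of the genotype labels.

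The first comparison asked what IFNγ changes in WT microglial cells. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), a guanylate-binding protein that attacks the vacuoles of intracellular pathogens, rose by 8.45 on the log2 scale (SE 0.85, adjusted p = 9.56e-07), from 3.35 ± 0.73 to 11.80 ± 1.40 (SD, n = 3). Iigp1, an immunity-related GTPase, rose by 9.80 (SE 0.80), Gbp3 by 7.90 (SE 0.52) and Ly6a, a surface protein of activated lymphoid and myeloid cells, by 8.90 (SE 0.76). Cxcl9, a chemokine that draws T cells, had 1 read over the 3 medium libraries and 10.29 ± 1.47 with IFNγ, a ratio of 5955 (95% counting interval 1068 to 235264). Acod1, the enzyme that makes itaconate, rose by 7.41 (SE 0.37, adjusted p = 2.31e-10) to 13.04 ± 0.90.

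The guanylate-binding proteins rose in 6 of 7 measured members, and 7 rose adjusted over the list alone (camera adjusted p = 1.01e-11). Of the immunity-related GTPases 15 of 17 rose, 16 adjusted over the list alone (camera adjusted p = 6.11e-21). Tgtp2, with no read in medium, was at least 474-fold higher, and Gm4951 had a ratio of 1009 (279 to 8342) over 2 reads. All 36 measured antiviral genes rose, over all genes and adjusted over the list alone (camera adjusted p = 4.4e-48). Among them were Ifi44 with a ratio of 1669 (299 to 65991) over 1 read and Ifi205 with 361 (99.3 to 2985) over 2 reads. In the IFNγ receptor, STAT and IRF list 9 of 18 members rose, 12 adjusted over the list alone (camera adjusted p = 3.2e-09). The transcription factors Irf7 and Irf1 rose by 4.87 (SE 0.46) and 3.91 (SE 0.45). The receptor chain Ifngr1 differed by -0.06 (SE 0.34, adjusted p = 0.946).

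Antigen presentation rose in both classes. MHC class I and its processing rose in 17 of 19 members, 19 adjusted over the list alone (camera adjusted p = 1.08e-27). The immunoproteasome subunit Psmb9 rose by 5.42 (SE 0.38) and H2-T23 by 4.38 (SE 0.44). MHC class II rose in 5 of 12, 8 adjusted over the list alone (camera adjusted p = 1.85e-06). H2-Aa and H2-Eb1 had no read in medium and were at least 94.0-fold and 83.2-fold higher with IFNγ. Ciita, the master regulator of class II, had 1 read in medium and a ratio of 241 (42.7 to 9585) but did not pass (adjusted p = 0.0515). Its reads with IFNγ were 73, 99 and 0 in A, B and C, and it passed without WT IFNγ C (adjusted p = 1.04e-05). Of 13 chemokines 6 rose and 3 fell, 7 and 3 adjusted over the list alone (camera adjusted p = 7.54e-05). Ccl12 had a ratio of 523 (93.3 to 20722) over 1 read, and Ccl24, Ccl9 and Cxcl14 were lower at -1.70, -1.54 and -0.79.

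TNF and NF-kB signalling rose in 7 of 25 members, 11 adjusted over the list alone (camera adjusted p = 2.24e-07), among them the adhesion molecule Icam1 (1.87, SE 0.35) and the inhibitor Nfkbie (2.36, SE 0.64). Tnf itself differed by 0.96 (SE 0.36, adjusted p = 0.121; 0.0126 without WT IFNγ C). Of 33 cell death genes 12 rose, 16 adjusted over the list alone (camera adjusted p = 1.85e-08). The nucleic acid sensor Zbp1 was at least 325-fold higher over no read in medium, the inflammatory caspase Casp4 rose by 4.42 (SE 0.43), and Casp8 differed by 0.19 (SE 0.22, adjusted p = 0.699). Antimicrobial effectors rose in 4 of 11, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000378), among them the NADPH oxidase subunit Cybb (2.47, SE 0.18). The nitric oxide synthase Nos2 had no read in medium, was at least 26.2-fold higher on average, and did not pass (adjusted p = 0.079). It had 36, 20 and 0 reads in WT IFNγ A, B and C and passed without C (adjusted p = 0.000459). Serpina3f, a protease inhibitor, rose by 8.24 (SE 0.72), and Slamf8, a receptor of myeloid cells, was at least 550-fold higher over no read.

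Complement and microglial identity genes went both ways. In complement and coagulation 6 of 14 rose and 1 fell, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00636). C1ra and C3 rose by 4.07 (SE 0.84) and 4.06 (SE 0.44), and F13a1, a clotting factor subunit of macrophages, fell by 3.94 (SE 0.76). Among 31 identity genes 11 rose and 3 fell, 14 and 3 adjusted over the list alone (camera adjusted p = 0.000111). The scavenger receptor Cd36 and the receptor kinase Axl rose by 4.58 (SE 0.52) and 5.12 (SE 0.72), while the mannose receptor Mrc1 fell by 2.86 (SE 0.76, adjusted p = 0.0255). Other genes with large falls were Ltc4s, which makes leukotriene C4 (-3.70, SE 0.85), Nanos1 (-3.44, SE 0.58), Aaed1 (-3.30, SE 0.63), the lipid transporter Abca9 (-3.05, SE 0.41) and Asb10 (-3.01, SE 0.41). Slc36a2, an amino acid transporter, kept 2 reads with IFNγ and was higher in medium by a ratio of 52.4 (14.2 to 437).

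Cholesterol biosynthesis fell in 8 of 23 members, 12 adjusted over the list alone (camera adjusted p = 1.59e-07), with the enzymes Idi1 at -1.44 (SE 0.40) and Lss at -1.17 (SE 0.27). The integrated stress and unfolded protein response rose in 6 of 26, 10 adjusted over the list alone (camera adjusted p = 3.92e-06), led by Trib3 (2.53, SE 0.50) and Ddit3 (2.14, SE 0.36). In the cell cycle list 2 of 35 fell and 1 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.000662, downward): the proliferation marker Mki67 (-1.31, SE 0.28), the spindle motor Kif11 (-1.01, SE 0.19) and the cyclin Ccnd1 (0.78). The lysosome list rose in 5 of 37, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0011), Ctsc by 1.32 (SE 0.25) and Npc2 by 0.96 (SE 0.19), but its adjusted p = 0.22 with an estimated correlation. Glycolysis rose in 1 of 19, Eno1 (0.67, SE 0.17), and in 4 adjusted over the list alone (camera adjusted p = 0.00328), with an adjusted p = 0.229 with an estimated correlation.

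The remaining 5 lists were not called by camera. The autophagy list had 0 of 38 members called by limma, 0 adjusted over the list alone, 8 at an unadjusted p under 0.05 and 0 by voom (camera adjusted p = 0.538). The cargo receptor Sqstm1 differed by 0.56 (SE 0.20, adjusted p = 0.111). Of 16 p53 targets Cdkn1a, Plk2 and Mdm2 rose (1.62, 1.64 and 1.01) and Sesn1 fell (-1.40), 3 and 1 adjusted over the list alone as well (camera adjusted p = 0.0963). Of 24 NRF2 genes Blvrb rose (1.09) and the glutathione transferase Gstm1 fell (-1.26), 1 and 2 adjusted over the list alone (camera adjusted p = 0.735). Of 5 nuclear-retained RNAs Kcnq1ot1 fell (-1.002), 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.793). Of 13 immediate early and heat shock genes Zfp36 fell (-1.17), 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.195).

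In total, limma called 730 genes in WT cells, 497 higher and 233 lower with IFNγ, against 2184 at an unadjusted p under 0.05. The count was 448 without WT medium B, 424 and 428 without WT IFNγ A or B, and 1119 without the 2 IFNγ libraries of letter C, a choice made after the data were seen. Higher and lower genes numbered 391 and 113, 347 and 101, and 420 and 141 without WT medium A, B or C. They numbered 329 and 95, 320 and 108, and 621 and 463 without WT IFNγ A, B or C. Leaving out single libraries ended the calls of Mrc1 (adjusted p = 0.151 without WT IFNγ A), Idi1 (0.13 without WT medium B), Nfkbie (0.162 without WT medium B), Ltc4s (0.0547 without WT IFNγ A), Lss (0.0977 without WT medium B), Eno1 (0.0666 without WT IFNγ A), Blvrb (0.12 without WT medium A) and Kcnq1ot1 (0.148 without WT medium A).

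**Figure D1:**
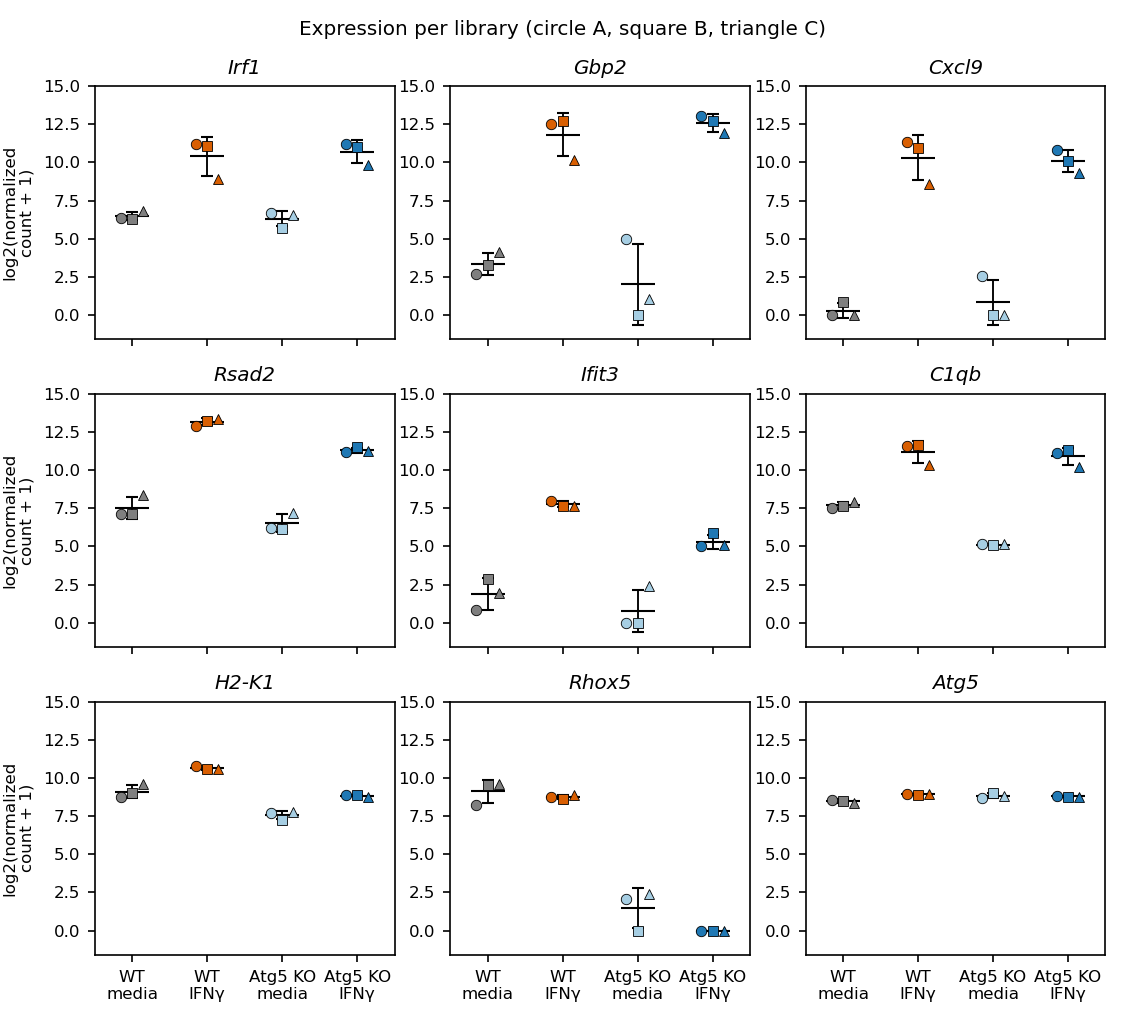
Expression of 9 genes in each of the 12 libraries. The y axis is log2 of the normalised count plus 1, points are libraries of replicate A (circle), B (square) and C (triangle), and bars give the group mean and SD of 3 libraries. Irf1, Gbp2 and Cxcl9 were lower in WT IFNγ C than in A and B, while Rsad2 stood at 12.91, 13.23 and 13.36 in WT IFNγ A, B and C. Rhox5 was present in every WT library and at 0 in the 3 KO IFNγ libraries.

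The same question was put to Atg5 KO cells. Gbp2 rose by 10.56 (SE 0.85, adjusted p = 5.84e-08) to 12.57 ± 0.58 (SD, n = 3), Ly6a by 9.78 (SE 0.76), Serpina3f by 9.44 (SE 0.72), Iigp1 by 8.99 (SE 0.80), Serpina3g by 8.28 (SE 0.79) and Acod1 by 7.06 (SE 0.37, adjusted p = 3.45e-10). Cxcl9 had 3 reads in medium and a ratio of 1038 (355 to 5037). Tgtp2 and Slamf8, with no read in medium, were at least 343-fold and 283-fold higher. Cd36 had 2 reads in medium and a ratio of 352 (97.1 to 2910), and C1qa, a subunit of the complement initiator C1q, rose by 6.43 (SE 0.58).

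All 7 guanylate-binding proteins rose, over all genes and adjusted over the list alone (camera adjusted p = 3.99e-13), Gbp3 by 8.19 (SE 0.52). Of the immunity-related GTPases 16 of 17 rose, and 16 adjusted over the list alone (camera adjusted p = 1.52e-26), and Gm12250 had a ratio of 891 (246 to 7360) over 2 reads. Antiviral genes rose in 33 of 36 members, 36 adjusted over the list alone (camera adjusted p = 1.01e-41). Ifitm3, which blocks virus entry, rose by 6.78 (SE 0.55), and Mx1 by at least 57.5-fold over no read. In the IFNγ receptor, STAT and IRF list 10 of 18 rose, and 10 adjusted over the list alone (camera adjusted p = 1.03e-10). Irf1 rose by 4.38 (SE 0.45) and the feedback inhibitor Socs1 by 4.62 (SE 0.76), while Ifngr1 differed by 0.13 (SE 0.34, adjusted p = 0.884). All 19 MHC class I and processing genes rose, over all genes and adjusted over the list alone (camera adjusted p = 1.52e-26), Psmb9 by 4.17 (SE 0.38) and H2-T23 by 4.12 (SE 0.44). Class II rose in 8 of 12, and in 8 adjusted over the list alone (camera adjusted p = 2.57e-07). H2-Aa was at least 47.7-fold and Ciita at least 36.1-fold higher over no read (adjusted p = 0.0145 for Ciita), and H2-DMa had a ratio of 91.1 (24.9 to 757) over 2 reads.

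Of 13 chemokines 7 rose and Ccl9 fell (-3.07), 8 and 3 adjusted over the list alone (camera adjusted p = 8.81e-05), and Ccl12 was at least 79.1-fold higher over no read. TNF and NF-kB signalling rose in 8 of 25, 13 adjusted over the list alone (camera adjusted p = 3e-07), including Relb (1.94, SE 0.29), Icam1 (1.87, SE 0.35) and Tnf (1.44, SE 0.36, adjusted p = 0.0151). Cell death genes rose in 12 of 33, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.96e-06). Zbp1 had a ratio of 430 (76.8 to 17019) over 1 read, Casp4 rose by 4.28 (SE 0.43), and Casp8 differed by 0.42 (SE 0.22, adjusted p = 0.329). Among 11 antimicrobial effectors 5 rose and the haemoglobin-binding Hp fell (-2.92), 6 and 1 adjusted over the list alone (camera adjusted p = 0.000453). Nos2 was at least 27.8-fold higher over no read (adjusted p = 0.00816).

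Identity genes rose in 12 of 31 and fell in 2, 15 and 4 adjusted over the list alone (camera adjusted p = 6.15e-06). Complement genes rose in 6 of 14 and fell in 2, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0074). F13a1 kept 2 reads with IFNγ and was higher in medium by a ratio of 153 (41.8 to 1266). Slc36a2 and Klhl30 had no read with IFNγ and were at least 40.9-fold and 34.5-fold lower. The other large falls were in Lrrc17 (-3.37, SE 0.58), the peroxisomal transporter Abcd2 (-3.35, SE 0.56), Lsp1, an actin-binding protein of leukocytes (-3.33, SE 0.42), and Asb10 (-3.25, SE 0.41). Cholesterol biosynthesis fell in 6 of 23, 8 adjusted over the list alone (camera adjusted p = 3.49e-07), with the enzymes Mvd at -1.19 (SE 0.24) and Acat2 at -0.89 (SE 0.25). The stress response list rose in 4 of 26, 7 adjusted over the list alone (camera adjusted p = 0.000504), with Trib3 at 2.01 (SE 0.50) and Ddit3 at 1.41 (SE 0.36). Nuclear-retained RNAs rose in 2 of 5, and in 2 adjusted over the list alone (camera adjusted p = 0.0165), Malat1 by 1.28 (SE 0.25) and Neat1 by 1.196 (SE 0.345). The lysis left nuclei behind, so in any group the level of such RNAs here need not follow that of whole cells.

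The remaining lists were not called by camera in KO cells. The autophagy list again had 0 of 38 members called by limma, 0 adjusted over the list alone, 8 at an unadjusted p under 0.05 and 0 by voom (camera adjusted p = 0.598), with Sqstm1 at 0.12 (SE 0.20, adjusted p = 0.815) and Atg5 at -0.06 (SE 0.17, adjusted p = 0.891). Of 37 lysosome genes 3 rose, and 3 adjusted over the list alone (camera adjusted p = 0.286), Ctsc by 1.66 (SE 0.25) and Psap by 0.77 (SE 0.18). Of 24 NRF2 genes Blvrb (1.69, SE 0.28) and the cystine transporter Slc7a11 (1.33, SE 0.37) rose and Gstm1 fell (-1.32), 2 and 1 adjusted over the list alone (adjusted p = 0.965). Of 16 p53 targets 3 rose, Plk2 by 1.69 (SE 0.32), and Sesn1 fell by 1.51 (SE 0.29), 3 and 3 adjusted over the list alone (adjusted p = 0.969). Of 35 cell cycle genes Ccnb2 fell (-0.86, SE 0.24), and 0 passed adjusted over the list alone (adjusted p = 0.224). Of 19 glycolysis genes Pfkp (0.94, SE 0.20) and Pgk1 (1.04, SE 0.24) rose and Aldoc fell (-0.93), 2 and 2 adjusted over the list alone (adjusted p = 0.0516). Of 13 immediate early and heat shock genes limma called 0, 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 by voom (adjusted p = 0.0789).

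In total, limma called 808 genes in KO cells, 513 higher and 295 lower, against 2119 at an unadjusted p under 0.05. The count was 513 without KO medium A and 524 without KO IFNγ A. Higher and lower genes numbered 371 and 142 or 406 and 190 without KO medium A or B, and 356 and 168 or 435 and 191 without KO IFNγ A or B. Leaving out single libraries ended the calls of Nos2 (adjusted p = 0.0569 without KO IFNγ A), Ciita (0.0767 without KO IFNγ B), Tnf (0.0901 without KO IFNγ B), Ddit3 (0.117 without KO IFNγ A), Trib3 (0.0714 without KO medium A), Slc7a11 (0.18 without KO medium B), Acat2 (0.183 without KO medium A), Ccnb2 (0.185 without KO medium B), Neat1 (0.167 without KO IFNγ B), Psap (0.0512 without KO IFNγ C) and Pgk1 (0.0756 without KO IFNγ A). Voom ended those of Socs1 (0.0891), H2-DMa (0.103) and Ciita (0.161).

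The responses of the genotypes were then set side by side. Of the genes called, 324 rose in both genotypes, against 23.2 by chance, and 95 fell in both, against 6.26 by chance. Across the 1118 genes called in either genotype, 92.4% moved in the same direction, Pearson's r was 0.909, Spearman's rho 0.866 and the slope of the KO on the WT response 1.03. Across all 10981 genes r was 0.724 and rho 0.423. These are correlations across genes, which are not independent replicates. Hnrnph1, a splicing regulator picked after its values were seen, was the 1 gene called in opposite directions, at -0.85 (SE 0.24, adjusted p = 0.0393) in WT and 0.98 (SE 0.24, adjusted p = 0.0157) in KO cells.

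**Figure D2:**
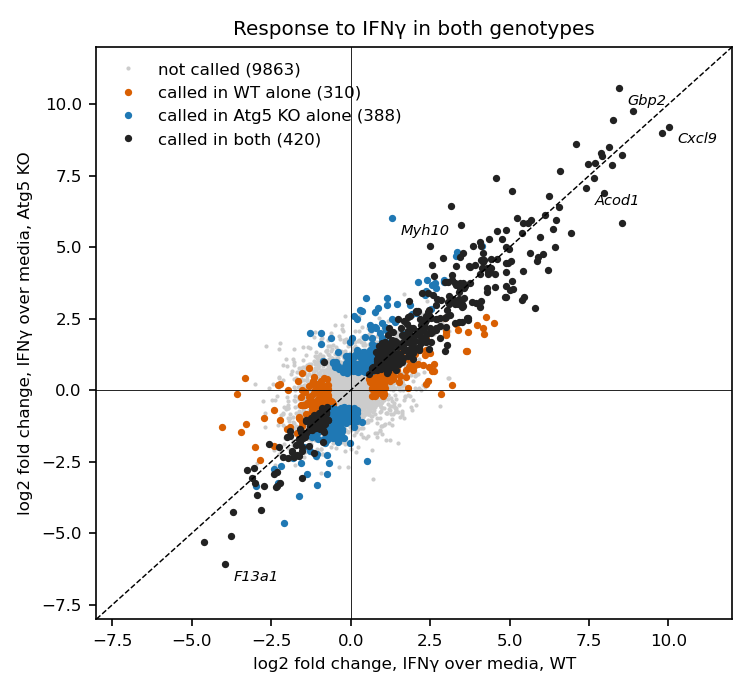
Log2 change with IFNγ in WT cells (x axis) and in Atg5 KO cells (y axis) for the 10981 tested genes, each point 1 gene, with the dashed line marking equal change. Black points are genes called in both genotypes, orange and blue points those called in WT or KO cells alone, and gray points those called in neither. The 1118 called genes lie along the line, with Gbp2 and Cxcl9 at the upper end and F13a1 at the lower end.

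Untreated KO and WT cells were compared to ask what differs between them before stimulation. The number of KO clones is not given, so loss of Atg5 and clone cannot be told apart in any difference between the genotypes. A small set of genes was nearly silent in KO cells. Rhox5 (ENSMUSG00000095180, chromosome X, 37804842 to 37808876), a homeobox gene, stood at 9.13 ± 0.76 in WT and 1.49 ± 1.30 in KO cells (SD, n = 3), a difference of -7.63 (SE 0.52, adjusted p = 3.65e-08). Slc32a1, a vesicular transporter of inhibitory neurotransmitters, Ptgfrn, Ppic and the non-muscle myosin Myh10 had no read in KO cells and were at least 168-fold, 63.7-fold, 34.9-fold and 39.9-fold lower. Tex101, a germ cell surface protein, differed by -6.34 (SE 0.64).

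C1q was lower in untreated KO cells: C1qb (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187) stood at 7.70 ± 0.22 in WT and 5.12 ± 0.01 in KO cells (-2.58, SE 0.30, adjusted p = 0.000107), with C1qa at -3.21 (SE 0.58, adjusted p = 0.0104) and C1qc at -2.09 (SE 0.32, adjusted p = 0.00227). These 3 genes made up the called members of the identity list, 3 lower of 31 and 9 adjusted over the list alone (camera adjusted p = 1.16e-06; adjusted p = 0.171 with an estimated correlation). They were also among the 4 called, all lower, of 14 complement genes, 4 adjusted over the list alone (camera adjusted p = 0.00439; adjusted p = 0.171 with an estimated correlation). The class I gene H2-K1 was lower by -1.53 (SE 0.21, adjusted p = 0.000757), the 1 called of 19 class I and processing genes, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.301). Of 36 antiviral genes Lgals3bp (-2.09, SE 0.33) and Usp18 (-1.96, SE 0.34) were lower, 9 adjusted over the list alone (camera adjusted p = 4.88e-06; adjusted p = 0.58 with an estimated correlation). Among 17 immunity-related GTPases Gm8995 (-1.58, SE 0.28) and 9930111J21Rik2 (-1.35, SE 0.28) were lower, 4 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.687 with an estimated correlation). Of 37 lysosome genes limma called 0, with 6 at an unadjusted p under 0.05, 0 by voom and 1 lower adjusted over the list alone (camera adjusted p = 0.0028; adjusted p = 0.58 with an estimated correlation).

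The genes higher in KO cells were fewer, 13 in all. Among them were the calcium-binding S100a6 (2.53, SE 0.33, adjusted p = 0.000332), Nr2f1 (2.35, SE 0.51), Arhgdig (2.21, SE 0.41), the creatine kinase Ckb (1.71, SE 0.31), Plpp1 (1.52, SE 0.26), Cnppd1 (1.40, SE 0.18, adjusted p = 0.000304), Crim1 (1.31, SE 0.26) and the ubiquitin hydrolase Uchl1 (1.29, SE 0.26). Autophagy genes showed no difference past the threshold, with 0 of 38 called by limma, 3 at an unadjusted p under 0.05, 0 by voom and 0 adjusted over the list alone (camera adjusted p = 0.944). Irf1 (-0.18, SE 0.45, adjusted p = 0.965), Ifngr1 (-0.25, SE 0.34, adjusted p = 0.927), Tnf (-0.22, SE 0.36, adjusted p = 0.94), Sqstm1 (0.15, SE 0.20, adjusted p = 0.927) and Casp8 (-0.17, SE 0.22, adjusted p = 0.922) did not pass, and Nos2, Ciita and Cxcl9 were at or under 3 reads in both groups.

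In total, limma called 47 genes in untreated cells, 13 higher and 34 lower in KO, against 907 at an unadjusted p under 0.05. The count was 25, 24 and 26 without WT medium A, B or C. It was 23 in a fit of these groups alone (2 higher and 21 lower) and 30 by voom (10 higher and 20 lower). Higher and lower genes numbered 4 and 21, 5 and 19, and 8 and 18 without WT medium A, B or C, and 7 and 29, 8 and 26, and 6 and 33 without KO medium A, B or C. Leaving out single libraries ended the calls of Nr2f1 (adjusted p = 0.279 without WT medium B), Arhgdig (0.107 without KO medium B), Ckb (0.0794 without WT medium A), Plpp1 (0.0506 without WT medium A), Crim1 (0.215 without WT medium B), Uchl1 (0.159 without WT medium C), C1qa (0.0722 without WT medium A), Usp18 (0.067 without WT medium C), Gm8995 (0.0712 without WT medium C) and 9930111J21Rik2 (0.199 without WT medium C). Voom ended those of C1qa (0.514), Usp18 (0.32), Gm8995 (0.295), Myh10 (0.226) and Lgals3bp (0.231), and the fit of these groups alone that of H2-K1 (0.0828).

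With IFNγ present in both genotypes, the comparison asked whether stimulated KO cells reach the level of WT cells. Rhox5, Slc32a1, Ptgfrn and Ppic had no read in KO cells and were at least 464-fold, 119-fold, 63.8-fold and 39.2-fold lower, and Tex101 differed by -7.10 (SE 0.64). Myh10, with no read in untreated KO cells, stood at 6.71 in WT and 6.02 in KO cells with IFNγ (-0.69, SE 0.56, adjusted p = 0.666). Gpr141, an orphan receptor of myeloid cells (-4.11, SE 0.65), and the fatty acid carrier Fabp3 (-3.96, SE 0.52) were lower as well. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) stood at 10.65 ± 0.14 in WT and 8.84 ± 0.05 in KO cells (-1.81, SE 0.21, adjusted p = 0.000136). Between the treatments, 12 genes were lower in KO cells in both, against 0.096 by chance, and 3 were higher in both, S100a6, Cnppd1 and Arhgdig, against 0.0272 by chance.

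Rsad2, which encodes the antiviral enzyme viperin, stood at 13.17 ± 0.23 in WT and 11.31 ± 0.17 in KO cells (-1.85, SE 0.30, adjusted p = 0.00426). It was the 1 of 36 antiviral genes called over all genes, and 20 were lower adjusted over the list alone (camera adjusted p = 2.56e-13), but the adjusted p = 0.362 with an estimated correlation. Voom called 14 of them, 35 of 36 had lower means in KO cells, and the median difference was -0.97. The mean of the list was 8.40 ± 0.27 (SD, n = 3) in WT and 7.32 ± 0.24 in KO libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give. The guanylate-binding proteins had 0 of 7 members called by limma, with 0 at an unadjusted p under 0.05 and 0 by voom, and 0 adjusted over the list alone (camera adjusted p = 0.201). The immunity-related GTPases had 0 of 17 called, with 1 at an unadjusted p under 0.05, 0 by voom and 0 adjusted over the list alone (camera adjusted p = 0.259). Of 38 autophagy genes limma called 0, with 8 at an unadjusted p under 0.05, 0 by voom and 1 lower adjusted over the list alone (camera adjusted p = 0.294).

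Ccl5, a chemokine for T cells and monocytes, was lower by -2.61 (SE 0.38, adjusted p = 0.00173), the 1 called of 13 chemokines, 4 lower adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.373 with an estimated correlation). Of 37 lysosome genes limma called 0, with 18 at an unadjusted p under 0.05 and 0 by voom, and 10 were lower adjusted over the list alone (camera adjusted p = 9.69e-08; adjusted p = 0.362 with an estimated correlation). H2-K1 was the 1 called of 19 class I and processing genes, and the 1 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.589 with an estimated correlation). Mki67 was higher in KO cells by 1.31 (SE 0.28, adjusted p = 0.0384), the 1 called of 35 cell cycle genes, 2 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.373 with an estimated correlation). Of 31 identity genes limma called 0, with 6 at an unadjusted p under 0.05, 0 by voom and 1 lower adjusted over the list alone (camera adjusted p = 0.0295; adjusted p = 0.373 with an estimated correlation).

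Among the 23 genes higher in KO cells with IFNγ were also Arhgdig (2.34, SE 0.41), Carmil1 (2.07, SE 0.45), S100a6 (2.05, SE 0.33), Btbd3 (1.71, SE 0.38), Rpl14-ps1 (1.59, SE 0.33) and Wwox (1.55, SE 0.34). Tshz1 (1.50, SE 0.29), the lysosomal channel Mcoln3 (1.43, SE 0.24), Cnppd1 (1.41, SE 0.18), Kcnq1ot1 (1.35, SE 0.28) and the drug exporter Abcc1 (1.14, SE 0.23) were higher too. Irf1 (0.29, SE 0.45, adjusted p = 0.853), Cxcl9 (-0.22, SE 0.66, adjusted p = 0.934), Tnf (0.26, SE 0.36, adjusted p = 0.83), Nos2 (1.52, SE 1.097, adjusted p = 0.621), Ciita (0.63, SE 1.24, adjusted p = 0.887), Ifngr1 (-0.05, SE 0.34, adjusted p = 0.977), Sqstm1 (-0.29, SE 0.20, adjusted p = 0.602) and Casp8 (0.06, SE 0.22, adjusted p = 0.958) did not pass.

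In total, limma called 54 genes between the treated genotypes, 23 higher and 31 lower in KO, against 1317 at an unadjusted p under 0.05. The count was 24, 23 and 83 without WT IFNγ A, B or C, 27 and 30 without KO IFNγ A or C, and 35 without WT medium B. The balance turned without WT IFNγ C, to 47 higher and 36 lower, and without KO IFNγ B, to 37 higher and 26 lower. Higher and lower genes numbered 8 and 16 or 9 and 14 without WT IFNγ A or B, 10 and 17 or 8 and 22 without KO IFNγ A or C, and 14 and 21 or 14 and 22 without WT medium B or C. With other settings the count was 32 with no filter (10 higher and 22 lower) and 86 with 8 added before the log (34 and 52). It was 29 in a fit of these groups alone (6 and 23), 84 by voom (29 and 55) and 89 with the replicate letter as a block (36 and 53). The count was 18 (6 higher and 12 lower) without both IFNγ libraries of letter C, which ended the calls of Rsad2 (adjusted p = 0.0868), Ccl5 (0.0511), S100a6 (0.0521) and Mcoln3 (0.0521). Leaving out single libraries ended those of Mki67 (0.185 without KO IFNγ C), Arhgdig (0.0774 without KO IFNγ A), Carmil1 (0.164 without KO IFNγ A), Btbd3 (0.219 without KO IFNγ C), Rpl14-ps1 (0.174 without KO IFNγ A), Wwox (0.145 without WT IFNγ A), Tshz1 (0.122 without WT IFNγ A), Kcnq1ot1 (0.129 without KO IFNγ C) and Abcc1 (0.153 without KO IFNγ C).

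The last comparison tested whether the response to IFNγ itself differed between the genotypes. C1qb rose by 3.48 (SE 0.30) in WT and 5.77 (SE 0.30) in KO cells, from unequal starting levels to 11.19 and 10.89. Mki67 fell by 1.31 in WT and differed by 0.79 in KO cells, which did not pass (adjusted p = 0.0957). Their differences in response, 2.28 (SE 0.43) and 2.10 (SE 0.39), each had an adjusted p of 0.106, the smallest reached, as did Hnrnph1 (1.82, SE 0.34) and Myh10. Myh10 had the smallest unadjusted p (9.98e-06) and went from 5.40 to 6.71 in WT cells and from no read to 6.02 in KO cells (adjusted p = 0.19 and 4.35e-07 for the responses). These genes were picked after their values were seen. Irf1 (0.47, SE 0.64, adjusted p = 0.911), Cxcl9 (-0.79, SE 0.94, adjusted p = 0.894), Tnf (0.48, SE 0.50, adjusted p = 0.878), Sqstm1 (-0.44, SE 0.29, adjusted p = 0.775), Casp8 (0.23, SE 0.32, adjusted p = 0.914), Ifngr1 (0.20, SE 0.49, adjusted p = 0.961) and Atg5 (-0.50, SE 0.24, adjusted p = 0.702) did not pass either.

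Limma called 0 genes for this difference, with 792 at an unadjusted p under 0.05, and voom called 0. With the replicate letter as a block limma called 1, Myh10 (adjusted p = 0.0325). Without both IFNγ libraries of letter C limma called 3, Myh10 (adjusted p = 0.00228), C1qb (0.00325) and Mki67 (0.0466). In simulated data of the same size the test recovered 61% of genes with a 4-fold and 10% with a 2-fold difference in response. Those data held no weakly responding library and gave genes of like level 1 shared spread, so recovery in the real data may differ. Among the lists, camera called the immunity-related GTPases, in which 15 of 17 members rose more in KO cells (adjusted p = 0.0119; adjusted p = 0.846 with an estimated correlation). Limma called 0 of them over all genes, with 4 at an unadjusted p under 0.05, 0 by voom and 1 adjusted over the list alone. Leaving out WT IFNγ C brought a call for Mki67 (adjusted p = 0.031), KO medium B for C1qa (0.0351), KO IFNγ B for Hnrnph1 (0.00428), Mki67 (0.0303) and AI506816 (0.0483), and KO IFNγ C for Myh10 (0.00108) and C1qb (0.0238).

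The position of the genes was examined after the genotype differences had been seen. Chromosome 2 had 889 tested genes at a median KO to WT difference of -0.14 in medium and -0.16 with IFNγ (permutation p of 1e-04 in each, the smallest that 10000 random gene sets can give). Chromosome 12 (380 genes, 0.056 and 0.145) and chromosome 16 (351 genes, 0.084 and 0.086) were shifted upward. Against random gene sets, chromosome 18 (0.073, adjusted p = 0.032) and chromosome 7 (-0.043, adjusted p = 0.0424) passed with IFNγ. They did not pass in medium (adjusted p = 0.897 and 0.823). Among genes with a mean of at least 6 the medians of chromosome 2 were -0.13 and -0.12 over 650 genes, those of chromosome 12 were 0.077 and 0.153 over 282, and those of chromosome 16 were 0.055 and 0.091 over 249. Of the 12 genes lower in KO cells in both treatments 2 lie on chromosome 2, among them Slc32a1, against 0.974 for its share of genes.

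**Figure D3:**
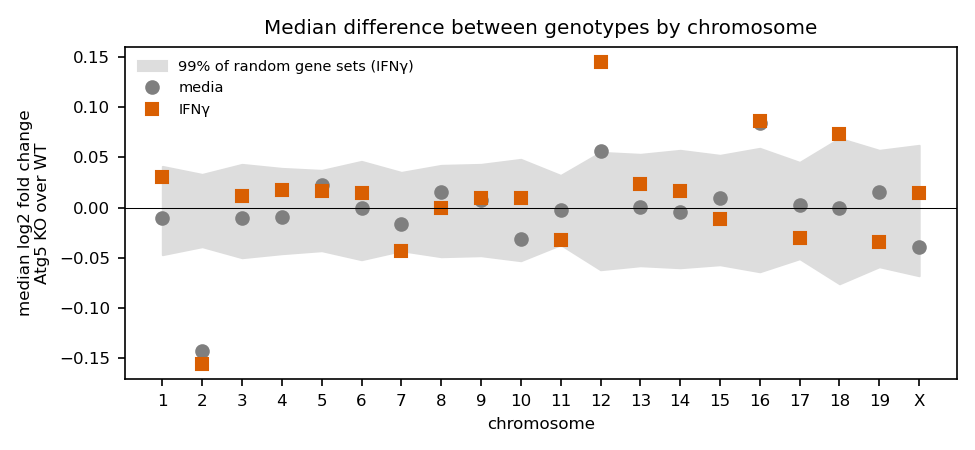
Median log2 difference between Atg5 KO and WT cells over the tested genes of each chromosome, in medium (gray circles) and with IFNγ (orange squares). The band holds 99% of random gene sets of the same size with IFNγ. Chromosome 2 lies at -0.14 and -0.16, below the band in both treatments. Chromosomes 12 and 16 lie above it in both treatments, and chromosome 18 with IFNγ. No band is drawn for the values in medium.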

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

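The tests of WT IFNγ C and the fits without letter C were chosen after the results were seen; the count over other splits of the libraries was planned. One result drew attention because the response of a gene list differed between the genotypes in a test of the difference itself. Camera called the immunity-related GTPases for a larger rise in KO cells (adjusted p = 0.0119), with 15 of 17 members rising more there. It was 0.846 with an estimated correlation, 0.764 by fry and 0.124 without the 2 IFNγ libraries of letter C. Of 100 drawn splits of the genotypes within treatments, 86 called at least as many lists. The real split called 1 and others up to 14. For single genes, 792 had an unadjusted p under 0.05 in the real split and up to 1645 in others. In 16 of 100 splits the number was as high. Labels were redrawn separately in each treatment, so a constant difference between the genotypes could enter the difference in response of a drawn split. These splits therefore cannot measure chance, which is not excluded.

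The larger rise may come from WT IFNγ C, whose response was weak, but the level in medium enters it too. Over the guanylate-binding proteins and GTPases together, the mean log2 in medium was 2.05 in WT and 1.71 in KO cells. Both lie under the filter's log2 of 3. With IFNγ the means were 7.07 and 7.57 (exact permutation p = 0.4 in medium and 0.8 with IFNγ). Strongly induced genes were those with a log2 of at least 7 and a log2 rise of at least 3 in both A and B. Over 82 such genes WT IFNγ C held a median of 42.6% of the rise in A and B, from 0.486% for Tgtp1 to 123% for Rtp4. KO IFNγ C held 66.4% of its own over 61 genes. RNA of untreated cells mixed in at 1 share is argued against, since the spread of these shares was 3.78 times that between A and B. In KO cells it was 1.61 times. The choice of genes by A and B can narrow the spread between them and so raise this ratio, by an amount that was not tested. An exchanged label with an untreated library is argued against as well, as the guanylate-binding proteins and GTPases of WT IFNγ C stood 3.09 above the highest untreated library. So is lower depth, because the IFNγ library with the fewest reads, WT IFNγ A, held them at 7.67. A weaker or shorter stimulus shared by the letter C cultures stays open, because the shares of the 2 genotypes correlated across 57 genes (rho 0.383, permutation p = 0.00384) but common kinetics of the genes would give that too; no biological explanation within a group was tested.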

How the results depend on the processing

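The counts were recomputed under each alternative, and voom and the fits without letter C were chosen after seeing the data. The cause was not tested unless named. Genes called with IFNγ numbered 730 in WT cells, 1119 without the letter C libraries and 424 to 1084 without single libraries; in KO cells they numbered 808 and 513 to 959. Between untreated genotypes 47 became 23 with only the compared groups, which leaves fewer degrees of freedom, 30 by voom, and 24 to 57 without single libraries. Between treated genotypes 54 became 32 with no filter, 86 with 8 added before the log, 29 with only the compared groups, 89 with the replicate block, 84 by voom, 18 without letter C (16 of them among the 54) and 23 to 83 without single libraries. For the difference in response limma called 0 genes (792 at an unadjusted p under 0.05, voom 0), 1 with the block, Myh10 (adjusted p = 0.0325), 3 without letter C, and 0 to 3 without single libraries. The 18 correlations between same-letter libraries were small, from -0.064 to 0.219, with 2 over 0.1. Most of them were positive, while most of those between different letters were negative. Of the 12 libraries 9 correlated best with their own letter. The block also raised the counts with IFNγ to 815 in WT and 909 in KO cells, and to 56 between untreated genotypes. These values go with a letter effect, although the main fit left the letters out.

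Lists called between untreated genotypes, 5, became 0 with an estimated correlation and 1 by fry. Between treated genotypes 6 became 0 and 3, and 3 with the block. For the difference in response 1 became 0, 0, 3 with quantile normalisation and 0 without letter C.

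No named gene that was called changed sign under any setting. The calls between treated genotypes, 23 higher and 31 lower, turned to 47 higher and 36 lower without WT IFNγ C and to 37 higher and 26 lower without KO IFNγ B. The log2 change of at least 1 was applied to total counts only. Under every other setting that tested them, named genes passed in 44 of 52 cases with IFNγ in WT cells and 40 of 53 in KO cells. Klhl30, among these 40, was not tested under the stricter filter. Between genotypes they did in 9 of 23 cases untreated and 8 of 22 treated. The correlation of the responses ran from 0.889 to 0.916 without single libraries. Limits set by depth were not tested beyond the counting intervals and floors.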

Other observations

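The tests of an overall weaker response, of a lower level in untreated cells and of chromosomes against random genes were chosen after the results were seen; the counts over splits and the test of GC content and length were planned. Several genes were lower in KO cells under both treatments. Abhd6 and Ush1c were picked after their values were seen, while the rule named Gpr141 and Fabp3 for the treated comparison. The lipase Abhd6 differed by -3.65 (SE 0.79) in medium and -3.92 (SE 0.79) with IFNγ, Gpr141 by -3.97 (SE 0.65) and -4.11 (SE 0.65), Fabp3 by -2.52 (SE 0.52) and -3.96 (SE 0.52) and Ush1c by -1.32 (SE 0.22) and -1.13 (SE 0.22). Apoe, a lipid carrier of microglia, and the receptor Trem2 were also picked after their values were seen. With IFNγ Apoe fell by 1.59 (SE 0.23) in WT and 1.81 (SE 0.23) in KO cells, and Trem2 by 0.85 (SE 0.19) and 0.88 (SE 0.19).

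With IFNγ the antiviral list had a median difference of -0.97 between KO and WT cells, with lower means in KO cells for 35 of 36 members, 1 called over all genes and 20 adjusted over the list alone. Camera called the list (adjusted p = 2.56e-13) but not with an estimated correlation (adjusted p = 0.362), and its mean per library had an exact p of 0.1, the smallest possible here. A weaker response to IFNγ overall in the KO libraries is argued against, since the 24 guanylate-binding proteins and GTPases had a median of 0.45, a gap of 1.43 (SE 0.214), and medians of 0.051 and -1.05 without letter C. A trend with GC content and transcript length is argued against too, as the antiviral median was -0.97 (SE 0.126, also over genes) with the trend removed. A lower level already in untreated cells stays open. In medium 30 of 36 had lower means in KO cells, with 2 called over all genes and 9 adjusted over the list alone. Camera called the list there (adjusted p = 4.88e-06), but not with an estimated correlation (adjusted p = 0.58). The mean per library differed by -0.617 in medium (exact permutation p = 0.2) and by -1.074 with IFNγ. For the difference in response limma called 0 of the 36, with 5 at an unadjusted p under 0.05 and 0 by voom. Camera did not call the list for it. Across genes the differences in the 2 treatments had a rho of 0.291 (permutation p = 0.0844), which cannot show a shift shared by all. Clone and genotype are not separable here.

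The genes of chromosome 2 stood lower in KO cells, by a median of -0.143 in medium. Chance over genes is argued against, since random sets of the same size did not reach its median of -0.156 with IFNγ. Of the 10 splits of the 6 untreated libraries 1, the real split, had a shift as large (-0.135 against at most 0.054 in size for the others), and 10 splits are too few for a share under 0.05. Without the called genes 99.8% of the shift was left, but these are too few to move a median over 889 genes, so this decides nothing. A change in copy number of part of the chromosome in the KO line may be a candidate explanation, which is untested because no DNA was sequenced, and it would not be told apart from an effect of Atg5.

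Other splits of the 6 libraries were counted for each comparison, and 10 splits cannot give a share under 0.05. Every other split mixes the compared groups, which puts their difference into the residual spread. Low counts there can follow from this alone, so the splits cannot measure chance. The real splits called 730, 808, 47 and 54 genes, in 1, 1, 1 and 1 of 10 splits, and the highest others 0, 1, 1 and 49. The split with 49 genes set WT IFNγ A and B with KO IFNγ B against the rest. For lists the real splits called 17, 15, 5 and 6, reached in 1, 1, 4 and 3 of 10 splits, and the highest others 15, 11, 7 and 11.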
